A study of Arabidopsis thaliana with 42 samples.

How the data were processed

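RNA was sequenced from whole Arabidopsis thaliana seedlings, 42 libraries in 21 groups of 2. Per the file headers, the authors counted reads per gene with featureCounts 2.0.3 in paired mode without counting read pairs, unstranded, with no option for reads that map to several places, against TAIR10 gene models. The deposited values are counts, whole numbers for 33602 genes in each library. The labels name HISAT2 2.2.1, StringTie 2.1.4 and edgeR among the authors' tools. Library totals were checked on the files and ranged from 10021645 to 78607524 assigned reads. A count of 0 in 1 library allows up to 3 reads, which is 0.0779 to 0.295 CPM (reads scaled to a common library size) in the set of Col_0 and QK, 0.0345 to 0.0676 CPM in the set of Col-0, and 0.0413 to 0.132 CPM in the set of WT and dPrD2. Intervals and such floors cover counting error only and take reads as independent. Since the 2 mates of a fragment are counted as separate reads, a count of 0 would allow up to 6 reads if every fragment gave 2 reads, which doubles these floors.

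The group of each library came from its label alone. The names split the libraries into 3 sets, which were never fitted together: Col_0, QK and AtHSFA1adelPrDs in QK (14 libraries), Col-0 with a hyphen (4 libraries), and WT and dPrD2 (24 libraries). Each set was fitted with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood negative binomial model, 1 coefficient per group, TMM scaling). Genes were filtered by edgeR's filterByExpr with a minimum count of 10 and a minimum total of 15, which left 21872, 22074 and 22154 genes. The fits had 7, 2 and 12 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and an adjusted p under 0.05 counts as a call. The standard error of a log2 fold change was taken from its quasi-likelihood F statistic. There were 27 comparisons. 7 of them test the difference between 2 responses (an interaction). For WT and dPrD2 the controls are the mean of C1 and C2, and C1 and C2 alone were tried as alternatives. Libraries of different groups share a replicate number, and no block entered the model. In the first set the replicate number goes with a prefix in the file headers, 218R in every replicate 1 and 219R in every replicate 2, so the spread within groups includes any difference between these prefixes. What the prefixes mark is not stated. The headers of the other sets hold 1 prefix each.

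The gene lists, the comparisons, the test, the rule for naming genes and most alternatives were fixed before the data were examined. The 20 lists hold 220 genes: HSFA1 factors, other heat shock factors, small heat shock proteins, cytosolic chaperones and co-chaperones, organelle chaperones, the unfolded protein response of the endoplasmic reticulum, heat memory and acquired tolerance, HSFA1-dependent regulators and enzymes, touch and early stress regulators, jasmonate response, abscisic acid and drought response, salicylate and immune response, oxidative and mitochondrial stress, circadian clock, warm growth and auxin, flavonoid synthesis, photosynthesis, root markers, seed storage, and reference genes. Some genes stand in more than 1 list. Each list was tested against all other genes with camera in limma 3.58.1 with a correlation estimated per list, adjusted over all lists and comparisons of a set. The estimate depends slightly on the order of the groups in the model, which was alphabetical, and the reverse order was tried as an alternative chosen after seeing the data. A preset correlation of 0.01 and the rotation test fry were alternatives. Fry asks whether the genes of a list move, on balance, one way, and does not compare them with other genes. Where a list is called with the preset correlation and not with an estimated one, both values are given. For each list the number of calls over all genes tested and the number adjusted over the list alone are given.

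Named genes are the HSFA1 genes and HSFA2, up to 4 called members of each list with the largest change (or up to 2 abundant members, as values, where none was called), and the 8 highest and 5 lowest changes among called genes with an average log2 CPM of at least 2 and no overlap between the libraries compared. For comparisons with the mean of C1 and C2, the last condition was the same direction against each control, and interactions had no such condition. A gene with no reads in one arm is given as a lower bound of its fold, computed against 3 reads over that arm. Alternatives were RLE size factors, no filter, the Wald test of DESeq2 1.42.0, a fit of only the groups compared, a replicate block, and leaving out each library. A count of called genes was taken as unmoved when it stayed within 1.5 times its value. The edgeR fits were tested on simulated data of the same depth and spread with 200 changed genes. There they recovered 63.6% to 98.5% of changes of 4-fold, with 1.89% to 9.36% false calls. In the simulation all groups shared 1 mean profile, genes were drawn independently and no change exceeded 4-fold. Most real comparisons hold far more and larger changes, so these rates need not carry over to them. Tables were built with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and drawn with matplotlib 3.10.9. Gene names came from the reference annotation, which held 32835 of the gene identifiers.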

Results

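Seedlings were grown at 22 °C and shifted to 37 °C in a water bath or kept at 22 °C. In the first set, a line labelled Col_0 and a line labelled QK, described as the mutant hsfa1abde, were sampled at 22 °C and after 5 min and 15 min at 37 °C. A line named for HSFA1a with deleted prion-like domains in QK (AtHSFA1adelPrDs in QK) was sampled at 22 °C. The second set holds a line labelled Col-0 at 22 °C and at 37 °C, for a time the labels do not give. The third set holds the lines labelled WT and dPrD2 in 6 treatments. T seedlings were at 37 °C for 5 min on day 7, R seedlings were at 37 °C for 5 min on day 4 and back at 22 °C until day 7, and PT seedlings were heated on both days. C1 and C2 are controls with no heat on day 7 whose difference is not described, and the treatment P and the genetic make-up of the line labelled WT are not described either. Each of the 21 groups has 2 libraries, with 10021645 to 42609274 assigned reads in the first set, 51187751 to 73694556 in the second and 21712424 to 78607524 in the third. Levels are normalised read counts in CPM (mean ± SD), changes are log2 fold changes (± SE), and n = 2 libraries per group throughout. Of the 108 called changes between groups of libraries named here, 107 separate every library of one side from every library of the other, and HSFA1E in unheated dPrD2 and WT does not. The highest adjusted p among the called changes named is 0.0269. Genes were named largely for being called, and the highest and lowest for having no overlap, so these values largely follow from that choice. Nothing in the labels says whether the libraries of a group come from separate cultures, so p-values measure the spread between these samples, which can be technical.

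HSFA1 proteins are the heat shock transcription factors that start the heat response. HSFA1A (AT4G17750, chromosome 4, 9869818 to 9871603, minus strand of TAIR10) was read at 5.52 ± 0.584 CPM in Col_0, 6.07 ± 0.458 in QK, 168 ± 26.3 in AtHSFA1adelPrDs in QK, 58.2 ± 0.468 in WT C1 and 33.7 ± 0.0515 in dPrD2 C1. HSFA1B (AT5G16820) was read at 13.9 ± 1.73 CPM in Col_0 and 0.612 ± 0.517 in QK, and HSFA1D (AT1G32330) at 14.96 ± 1.65 and 2.16 ± 0.394. HSFA1E (AT3G02990) was read at 3.70 ± 0.473 CPM in Col_0 and 1.81 ± 0.360 in QK. In WT C1, HSFA1B, HSFA1D and HSFA1E were read at 1.41 ± 0.0992, 3.06 ± 0.478 and 0.928 ± 0.0602 CPM. In dPrD2 C1 they were read at 1.01 ± 0.0519, 3.04 ± 0.211 and 1.555 ± 0.0543 CPM. These levels are nearer to QK than to Col_0, though the sets were scaled apart, so the label WT need not mean a wild type like Col_0. The reads do not show whether a transcript makes a whole protein.

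**Figure D1:**
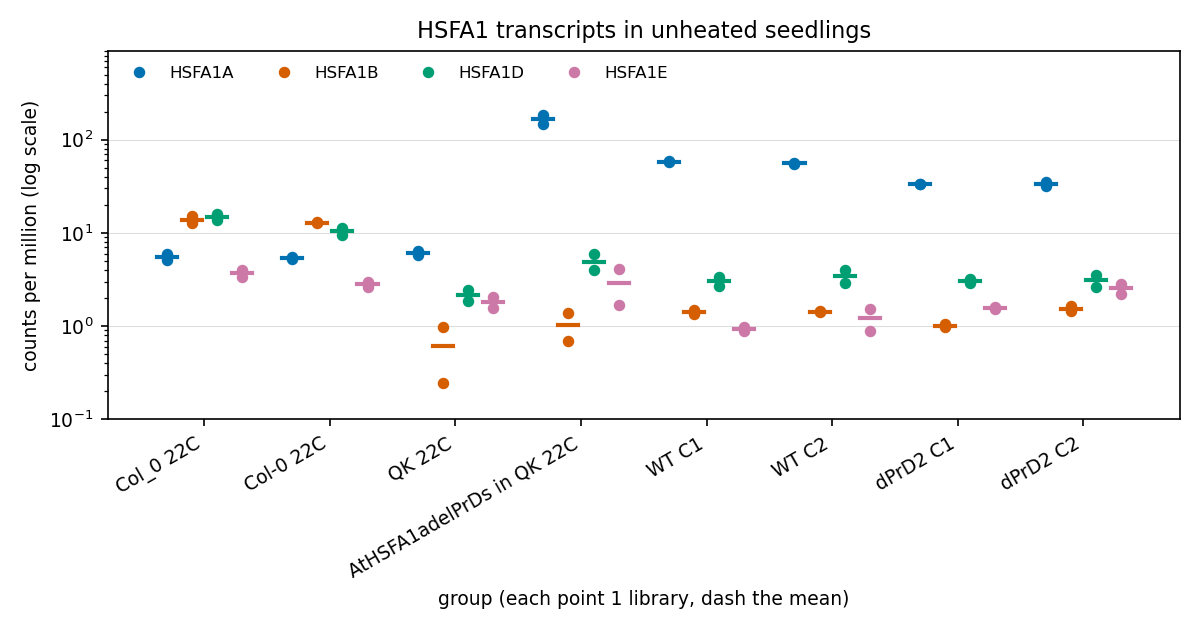
Read level of the 4 HSFA1 genes in unheated seedlings, in normalised read counts (CPM) on a log axis, with 1 point per library and a dash at the mean of the 2 libraries of each group. HSFA1A lies at 5.52 in Col_0, 168 in AtHSFA1adelPrDs in QK, 58.2 in WT C1 and 33.7 in dPrD2 C1.

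The first comparison asks how Col_0 seedlings respond to 5 min at 37 °C. HSFA2, a heat shock factor that sustains the response, rose from 4.38 ± 1.35 to 705 ± 193 CPM (log2 fold change 7.30 ± 0.39, adjusted p = 4.55e-08). HSFA7A rose by 6.59 ± 0.29, the class B heat shock factor HSFB2B rose by 3.54 ± 0.18, and HSFA7B, without reads at 22 °C, was at least 271-fold higher (136-fold against 6 reads, the floor if every fragment gave 2 reads). All 15 small heat shock proteins, which hold unfolding proteins in a state that can be refolded, rose, 15 adjusted over the list alone, with a median of 6.13. Of 22 cytosolic chaperones and co-chaperones 15 rose, 15 adjusted over the list alone, among them the disaggregase HSP101 (5.67 ± 0.38), the heat-inducible HSP90.1 (5.05 ± 0.32) and the BAG-domain co-chaperone BAG6 (6.19 ± 0.28). All 8 HSFA1-dependent regulators and enzymes rose, also adjusted over the list alone (8), such as the coactivator MBF1C (5.55 ± 0.26). Of 16 touch and early stress regulators 9 rose, 12 adjusted over the list alone, such as the zinc finger factor ZAT12 (3.40 ± 0.29). In the clock list 3 genes rose and 2 fell of 15, and 7 and 2 did so adjusted over the list alone. The morning factor LHY changed by -1.18 ± 0.14 and its relative RVE1 by 2.16 ± 0.29. Of 11 flavonoid genes 5 fell, 9 adjusted over the list alone.

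EdgeR called 1301 genes at 5 min, 815 up and 486 down, with 410 and 135 by at least 2-fold. Against all other genes, the small heat shock proteins gave adjusted p = 3.32e-28 with the preset correlation and adjusted p = 0.0864 with an estimated correlation. In the same order, the cytosolic chaperones gave 3.11e-21 and adjusted p = 0.108 with an estimated correlation, the HSFA1-dependent genes 1.93e-21 and 0.0783, the touch genes 1.28e-10 and 0.0820, and the flavonoid genes 4.55e-07 and 0.118. Over the comparisons of the first set, camera with an estimated correlation called 0 of 160 list tests (38 at an unadjusted p under 0.05), against 73 with the preset correlation. The estimate rests on few residual degrees of freedom (7 here and 2 in the Col-0 set, against 12 in the third). With so few, this test can miss lists that move, so 0 calls do not show that the lists stayed still. The clock list gave adjusted p = 0.0292 with the preset correlation and adjusted p = 0.254 with an estimated correlation. The Col_0 library of replicate 1 at 5 min held 0.132% of its reads on chloroplast-encoded genes, against 0.0258% in replicate 2. Without that library 554 genes were called, without replicate 2 at 5 min 861, and without replicate 2 at 22 °C 414.

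After 15 min at 37 °C, HSFA2 reached 3846 ± 216 CPM (9.75 ± 0.42), HSFA7A rose by 8.83 ± 0.31, and HSFA7B was at least 4063-fold higher (2031-fold against 6 reads). HSFA1E, a heat shock factor of the HSFA1 group, rose by 2.22 ± 0.32, and HSFA1A fell (-1.01 ± 0.17). Again all 15 small heat shock proteins rose, 15 adjusted over the list alone (median 9.55). Of 22 cytosolic chaperones 19 rose, 20 adjusted over the list alone, with HSP101 at 7659 ± 712 CPM (8.85 ± 0.43) and the HSP70 gene HSP70-5 up by 9.69 ± 0.35. Organelle chaperones also rose, 7 of 10 (7 adjusted over the list alone), led by the mitochondrial MTHSC70-2 (5.14 ± 0.20) and CLPB4 (5.06 ± 0.24). Heat memory genes, which keep plants tolerant after a first heat, rose in 14 of 15 cases, 15 adjusted over the list alone, such as the ascorbate peroxidase APX2 (9.12 ± 0.68). The test called 5505 genes, 2520 up and 2985 down, and 2976 without replicate 2 at 15 min. The small heat shock proteins gave adjusted p = 3.19e-24 with the preset correlation and adjusted p = 0.0970 with an estimated correlation. For the cytosolic chaperones these were 1.07e-29 and adjusted p = 0.0845 with an estimated correlation, for the organelle chaperones 3.50e-09 and 0.0820, and for the memory genes 2.13e-18 and 0.0970.

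The Col-0 set asks the same of the line labelled Col-0, in which 37 °C brought HSFA2 from 4.86 ± 0.0484 to 6246 ± 167 CPM (10.33 ± 0.18). All 15 small heat shock proteins rose, 15 adjusted over the list alone, led by HSP22.0, which resides in the endoplasmic reticulum (14.25 ± 0.25). HSP101 rose by 9.71 ± 0.22, CLPB4 by 5.21 ± 0.15 and HSFA1E by 1.76 ± 0.16. Of 12 abscisic acid and drought genes 9 rose, 9 adjusted over the list alone, such as the phosphatase HAI2 (4.14 ± 0.32). Of 8 salicylate and immune genes 5 fell, 6 adjusted over the list alone. Root markers fell in 6 of 10 cases, 6 adjusted over the list alone, such as the root hair expansin EXPA18 (-2.66 ± 0.20). EdgeR called 8020 genes, 3511 up and 4509 down, and 5050 without replicate 3 at 37 °C. The small heat shock proteins gave adjusted p = 1.64e-25 with the preset correlation and adjusted p = 0.148 with an estimated correlation. The abscisic acid genes gave adjusted p = 0.260, the salicylate genes 0.546 and the root markers 0.448 with an estimated correlation. Of the 862 genes called in both Col_0 at 5 min and Col-0, 94.8% changed in the same direction, and 471 genes rose in both where 125 would by chance. Of the 1092 genes called in Col_0 at 5 min and in the line labelled WT after T, 91.2% did, with 601 rising in both where 208 would by chance. For the 5523 genes called in Col-0 and in WT after T the values were 88.8%, 2228 and 846.

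QK at 22 °C was compared with Col_0 at 22 °C to see how the lines differ before heat. HSFA1B (-4.27 ± 0.35) and HSFA1D (-2.75 ± 0.24) were lower in QK. Small heat shock proteins were lower in 7 of 15 cases (7 adjusted over the list alone), and cytosolic chaperones in 15 of 22 (15 adjusted over the list alone), with 2 higher. The cytosolic HSP70-4 was at 12.01 ± 2.74 CPM in QK and 139.5 ± 4.39 in Col_0 (-3.56 ± 0.23), while HSP70-5 was higher (1.98 ± 0.28). All 18 photosynthesis genes were lower, 18 adjusted over the list alone, such as the antenna protein LHCB5 (-3.25 ± 0.24) and the Rubisco small subunit RBCS2B (-3.68 ± 0.22). Jasmonate genes were lower in 6 of 10 cases (6 adjusted over the list alone), led by the lipoxygenase LOX2 (-6.23 ± 0.51). Flavonoid genes were higher in 8 of 11 cases (8 adjusted over the list alone), such as the anthocyanin regulator PAP2 (3.46 ± 0.34). Seed storage genes were higher in 8 of 9 (9 adjusted over the list alone) and root markers in 7 of 10 (8 adjusted over the list alone), with 1 lower.

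The comparison of QK and Col_0 at 22 °C called 10299 of 21872 genes, 4649 higher and 5650 lower in QK. The photosynthesis genes gave adjusted p = 1.41e-14 with the preset correlation and adjusted p = 0.246 with an estimated correlation. For the jasmonate genes these were 0.00795 and adjusted p = 0.106 with an estimated correlation, for the flavonoid genes 0.000144 and 0.222, for the seed storage genes 0.00776 and 0.412, and for the root markers 0.0102 and 0.412. The cytosolic chaperones gave adjusted p = 0.538 with an estimated correlation and the small heat shock proteins 0.851. The seed storage gene SESA1 was read at 103.6 CPM in replicate 1 of QK at 22 °C and at 2.62 CPM in replicate 2. Genes on and off between the lines included AT5G27010, at least 810-fold higher in QK (405-fold against 6 reads), and AT3G05727, at least 1671-fold lower (836-fold against 6 reads).

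After 5 min at 37 °C, QK seedlings had 0.1002 ± 0.0389 CPM of HSFA2 and 3.56 ± 0.520 CPM of HSP101, against 0.799 ± 0.493 and 5.41 ± 2.55 at 22 °C, and neither change was called (adjusted p = 0.255 for HSFA2, from 6 and 26 reads, and 0.686 for HSP101). None of the 15 small heat shock proteins or of the 22 cytosolic chaperones was called by edgeR over all genes or adjusted over the list alone. At an unadjusted p under 0.05 edgeR had 1 small heat shock protein and 0 chaperones, and DESeq2 called 1 and 0. Of 16 touch and early stress regulators 3 rose, 8 adjusted over the list alone, such as the ethylene response factor ERF104 (2.07 ± 0.28) and the cold response factor CBF2 (4.19 ± 0.50). Of 11 flavonoid genes 3 fell, 7 adjusted over the list alone. CYP79F1, an enzyme of glucosinolate synthesis, fell from 21.1 ± 1.53 to 6.19 ± 1.12 CPM (-1.78 ± 0.19), and the bHLH factor AIF1 also fell (-1.85 ± 0.25). Without replicate 1 of QK at 22 °C, CBF2 (4.32) and ERF104 (2.37) no longer passed the test, nor did ERF104 without replicate 2 (1.88). EdgeR called 183 genes. It called 7 without replicate 1 and 40 without replicate 2 of QK at 22 °C, and 89 and 98 without replicates 1 and 2 at 5 min. The touch genes gave adjusted p = 1.01e-10 with the preset correlation and adjusted p = 0.0783 with an estimated correlation, and the flavonoid genes 1.93e-11 and 0.0820.

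After 15 min, QK seedlings raised genes of the endoplasmic reticulum and of early stress. BIP2, the HSP70 of the endoplasmic reticulum, rose from 426 ± 20.9 to 1713 ± 58.5 CPM (2.01 ± 0.17), and its close relative BIP1 by 1.91 ± 0.20. In the list of the unfolded protein response 8 of 12 genes rose, 11 adjusted over the list alone. Of 16 touch and early stress genes 15 rose, 16 adjusted over the list alone, with ERF104 up by 4.22 ± 0.29 and CBF2 by 6.67 ± 0.47. The mitochondrial stress gene OM66 rose by 4.03 ± 0.22, the drought and heat regulator DREB2A by 2.41 ± 0.23 and the salicylate regulator CBP60G by 4.33 ± 0.30. Of 15 small heat shock proteins 1 rose (1 adjusted over the list alone, adjusted p = 0.835 with an estimated correlation), and edgeR called 0 of 22 cytosolic chaperones (3 at an unadjusted p under 0.05, and 2 by DESeq2). HSFA2, not called, lay at 1.75 ± 1.27 CPM. EdgeR called 3130 genes, and 1661, 1703, 1353 and 1729 without QK replicate 1 and 2 at 22 °C and replicate 1 and 2 at 15 min. The unfolded protein response gave adjusted p = 4.37e-12 with the preset correlation and adjusted p = 0.0970 with an estimated correlation, and the touch genes 1.63e-20 and 0.0783. Reads on mitochondria-encoded genes were 0.454% in replicate 1 at 15 min and 0.103% in replicate 2.

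The difference between the heat responses of QK and Col_0 was tested directly. At 5 min the response of HSFA2 differed by -9.99 ± 1.05 (of which -2.69 is the change in QK, not called), that of HSP101 by -6.20 ± 0.53, of BAG6 by -6.54 ± 0.37, of MBF1C by -5.39 ± 0.39 and of HSFB2B by -3.03 ± 0.26, all lower in QK. Lower responses were called for 8 of 15 small heat shock proteins (14 adjusted over the list alone) and 12 of 22 cytosolic chaperones (15 adjusted over the list alone). Of 15 other heat shock factors 5 responded less (5 adjusted over the list alone), though the list's median of 0.18 has the opposite sign to its mean of -1.97. At 15 min the differences were -8.38 ± 0.91 for HSFA2, -8.54 ± 0.54 for HSP101, -9.44 ± 0.41 for HSP70-5 and -4.76 ± 0.25 for MTHSC70-2. Lower responses were called for 13 of 15 small heat shock proteins (13 adjusted over the list alone) and 19 of 22 cytosolic chaperones (19 adjusted over the list alone). In the unfolded protein response 8 of 12 genes responded more in QK and 1 less (10 and 1 adjusted over the list alone), with HSP90.7, the HSP90 of the endoplasmic reticulum, at 1.62 ± 0.21. CBP60G also responded more (3.69 ± 0.44), as did the auxin synthesis gene YUC8 (2.59 ± 0.42).

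These tests called 143 genes at 5 min, 127 of them lower in QK, and 1254 at 15 min. At 5 min 92 were called without replicate 1 of QK at 22 °C and 94 without replicate 1 of QK at 5 min. At 15 min 782 were called without replicate 2 of Col_0 at 15 min, 765 without replicate 1 of QK at 22 °C, and 717 and 788 without replicates 1 and 2 of QK at 15 min. At 5 min the small heat shock proteins gave adjusted p = 4.89e-22 with the preset correlation and adjusted p = 0.0845 with an estimated correlation, the cytosolic chaperones 2.07e-27 and 0.0865, and the other heat shock factors 0.00122 and 0.0845. At 15 min the small heat shock proteins gave adjusted p = 2.42e-21 with the preset correlation and adjusted p = 0.108 with an estimated correlation, the cytosolic chaperones 1.15e-38 and 0.0783, and the unfolded protein response 2.50e-09 and 0.131. Over the genes that rose in Col_0, the median ratio of the response in QK to that in Col_0 was 0.296 ± 0.050 at 5 min (815 genes) and 0.367 ± 0.0079 at 15 min (2520 genes). The value after ± is the SD over QK replicates with the Col_0 response held fixed, so it leaves out the spread of Col_0. The genes were chosen in the same Col_0 libraries, which can lower the ratio.

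**Figure D2:**
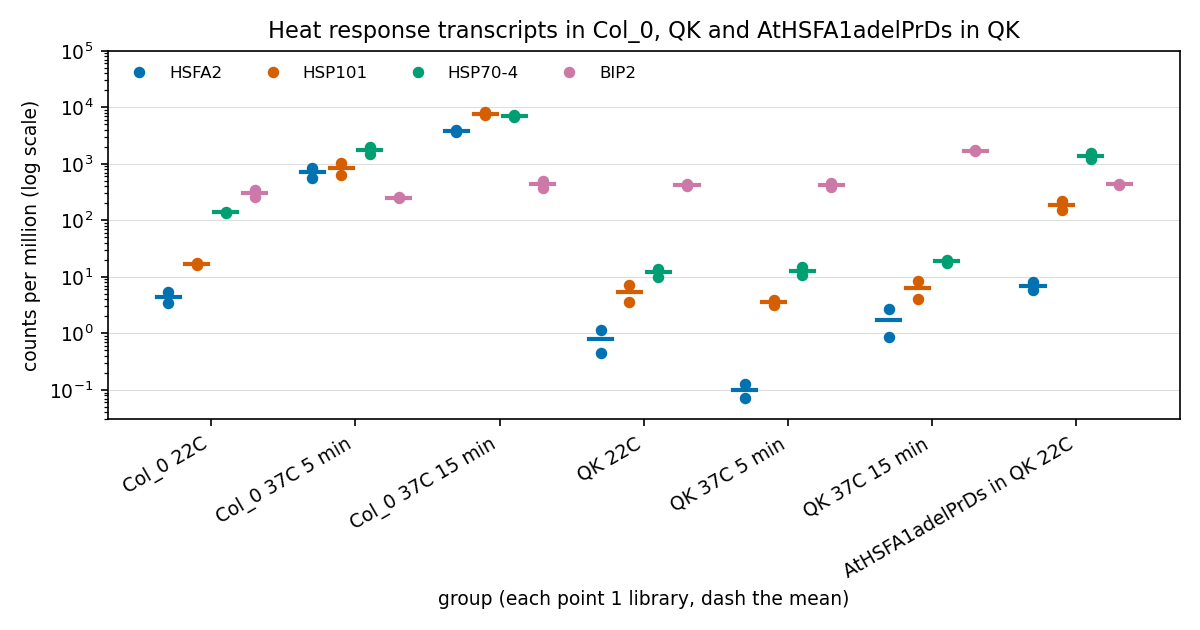
Read level of HSFA2, HSP101, HSP70-4 and BIP2 in the first set, in normalised read counts (CPM) on a log axis, with 1 point per library and a dash at the mean of the 2 libraries of each group. HSP101 reached 7659 in Col_0 at 15 min and 6.29 in QK, and lay at 186 in AtHSFA1adelPrDs in QK at 22 °C, while BIP2 was highest in QK at 15 min (1713).

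The line AtHSFA1adelPrDs in QK was compared with QK at 22 °C, so both were unheated. HSFA1A was 168 ± 26.3 CPM in this line and 6.07 ± 0.458 in QK (4.80 ± 0.15). All 15 small heat shock proteins were higher, 15 adjusted over the list alone, with a median of 10.11. The cytosolic HSP17.6C-CI lay at 2577 ± 772 CPM (12.60 ± 0.87), against 0.389 ± 0.0869 in QK and 2546 ± 324 in Col_0 heated for 15 min. This gene is not typical of the list. Relative to Col_0 at 15 min, the median level of the 15 in this line was 19.5%, with reads summed over the libraries of each group. Against QK, HSP70-4 was higher by 6.86 ± 0.26, HSP90.1 by 7.33 ± 0.37 and HSP101 by 5.18 ± 0.39, in a list of cytosolic chaperones in which 18 of 22 were higher and 1 lower (19 and 1 adjusted over the list alone). Of 15 heat memory genes 14 were higher and 1 lower, also adjusted over the list alone (14 and 1), with the galactinol synthase GOLS1 at 7.20 ± 0.34. HSFA2 lay at 6.94 ± 1.59 CPM (3.28 ± 0.50), against 3846 ± 216 in heated Col_0.

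Photosynthesis genes were higher in this line than in QK, 18 of 18 and 18 adjusted over the list alone, such as the Rubisco activase RCA (3.63 ± 0.29) and RBCS2B (3.31 ± 0.22). All 11 flavonoid genes were lower, 11 adjusted over the list alone, with the reductase DFR at -3.84 ± 0.31. Seed storage genes were lower in 6 of 9 cases (8 adjusted over the list alone) and root markers in 8 of 10 (9 lower and 1 higher adjusted over the list alone). EdgeR called 9751 genes, 5310 higher and 4441 lower. The small heat shock proteins gave adjusted p = 1.03e-09 with the preset correlation and adjusted p = 0.276 with an estimated correlation, the memory genes 1.63e-08 and 0.245, the photosynthesis genes 2.98e-15 and 0.238, and the flavonoid genes 8.35e-08 and 0.108. With an estimated correlation the cytosolic chaperones gave adjusted p = 0.305, the seed storage genes 0.497 and the root markers 0.412. The set holds no line with whole HSFA1A at this transcript level and no heated AtHSFA1adelPrDs in QK, so the effect of the deletion and its heat response were not measured.

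In the line labelled WT, T asks what 5 min at 37 °C on day 7 does. HSFA2 rose from 0.345 ± 0.0840 (C1) and 0.699 ± 0.527 (C2) to 741 ± 13.9 CPM (10.50 ± 0.10, adjusted p = 7.50e-45). All 15 small heat shock proteins rose, 15 adjusted over the list alone (median 9.18, list test adjusted p = 0.00224), such as HSP17.6A (11.02 ± 0.08). Of 22 cytosolic chaperones 20 rose, 20 adjusted over the list alone with 1 falling (adjusted p = 2.84e-05), including HSP101 (6.85 ± 0.04) and HSP90.1 (7.47 ± 0.05). In the list of HSFA1 factors 2 rose and 2 fell, also adjusted over the list alone (2 and 2, adjusted p = 0.577): HSFA1E by 4.99 ± 0.12, HSFA1D by 2.11 ± 0.14, HSFA1A by -0.57 ± 0.06 and HSFA1B by -1.44 ± 0.31. Oxidative and mitochondrial stress genes rose in 7 of 9 cases and fell in 1 (7 and 1 adjusted over the list alone, adjusted p = 0.0151), such as OM66 (1.64 ± 0.11). Root markers rose in 9 of 10 (9 adjusted over the list alone, adjusted p = 0.0356), such as the root hair wall protein LRX1 (1.26 ± 0.15). Of 7 reference genes 5 rose, 5 adjusted over the list alone, with a median of 0.19 and adjusted p = 0.162. PT, heated on days 4 and 7, brought HSFA2 to 829 ± 23.2 CPM (10.66 ± 0.10) and raised all 15 small heat shock proteins (15 adjusted over the list alone, adjusted p = 0.00218). EdgeR called 11633 genes after T, 5649 up and 5984 down (6129 and 5566 with RLE size factors, 5943 and 5405 with DESeq2, so the larger side depends on the scaling), and 11961 after PT.

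R asks what is left after 5 min at 37 °C on day 4 and a return to 22 °C. In WT the small heat shock protein HSP18.2 was 65.9 ± 1.96 CPM in R, 2.12 ± 0.208 in C1 and 2.62 ± 0.312 in C2 (4.80 ± 0.08). The 15 small heat shock proteins were all higher in R, 15 adjusted over the list alone (median 1.99, adjusted p = 0.00886). Of 15 heat memory genes 8 were higher, 9 adjusted over the list alone (adjusted p = 0.00205), with APX2 up by 4.26 ± 0.11 and GOLS1 by 2.34 ± 0.05. HSFA2 was not called, at 0.546 ± 0.127 CPM. Of 22 cytosolic chaperones 5 were higher and 3 lower (7 and 5 adjusted over the list alone, adjusted p = 0.577), and the list's median of -0.02 and mean of 0.11 differ in sign. HSP70-4 was higher by 1.12 ± 0.03. Jasmonate genes were higher in 4 of 10 cases (4 adjusted over the list alone, adjusted p = 0.00411), such as the storage protein VSP1 (1.27 ± 0.09), and abscisic acid genes in 9 of 12 (10 adjusted over the list alone, adjusted p = 0.00545). Abscisic acid genes also differed between the WT controls C1 and C2, so their rise in R need not be left from the heat on day 4. Over all genes, C1 and C2 of WT differed for 3822. Photosynthesis genes were lower in 16 of 18 cases (16 adjusted over the list alone, adjusted p = 0.0185), with RBCS1B at -0.65 ± 0.05, and root markers higher in 7 of 10 (7 adjusted over the list alone, adjusted p = 0.00915). EdgeR called 4340 genes, and 2657 and 2770 without replicates 1 and 2 of R.

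The contrast of PT with T asks whether levels after heat on day 7 differ when seedlings were also heated on day 4. It does not subtract what heat on day 4 leaves in R. A changed response to the heat on day 7 is therefore not told apart from transcripts left from day 4. The WT controls C1 and C2, with no heat on day 7, differed for 3822 genes in a way not described. A count of calls between PT and T alone therefore does not show an effect of heat on day 4. In WT, APX2 was 541 ± 4.79 CPM after PT and 168 ± 0.935 after T (1.69 ± 0.07), and GOLS1 1214 ± 0.698 and 695 ± 16.1 (0.80 ± 0.04). Of 15 small heat shock proteins 10 were higher after PT, 11 adjusted over the list alone (median 0.32, adjusted p = 0.0159), such as HSP22.0 (1.02 ± 0.06) and the mitochondrial HSP23.6 (0.68 ± 0.07). Of 15 memory genes 8 were higher, 10 adjusted over the list alone (adjusted p = 0.000960). HSFA2 was not called, at 829 ± 23.2 and 741 ± 13.9 CPM. Flavonoid genes were lower in 8 of 10 cases and higher in 1 (8 and 1 adjusted over the list alone, adjusted p = 0.000850), such as DFR (-1.11 ± 0.12). The root iron transporter IRT1 was higher by 3.60 ± 0.13 and the ferric reductase FRO2 by 2.95 ± 0.14, and the phosphatase PS2, induced by phosphate starvation, was lower (-3.37 ± 0.19). EdgeR called 3648 genes, and 2360 without WT T replicate 1, 2374 without WT PT replicate 1 and 2384 without WT PT replicate 2.

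Unheated dPrD2 was compared with unheated WT, each as the mean of C1 and C2. HSFA1A was lower in dPrD2 (-0.77 ± 0.05) and HSFA1E higher (0.88 ± 0.17). Of 15 small heat shock proteins 10 were higher, 11 adjusted over the list alone, such as HSP17.6A, at 5.25 ± 0.172 CPM in dPrD2 C1 and 0.378 ± 0.153 in WT C1 (3.27 ± 0.16). Cytosolic chaperones were lower in 13 of 22 cases and higher in 2 (16 and 3 adjusted over the list alone, adjusted p = 0.0155), such as the HSP70-HSP90 organising protein HOP2 (-0.55 ± 0.04). GOLS1 was higher (1.14 ± 0.04). Flavonoid genes were higher in 6 of 10 cases (6 adjusted over the list alone, adjusted p = 0.00357), and root markers in 8 of 10 with 1 lower (9 and 1 adjusted over the list alone, adjusted p = 0.0242). EdgeR called 6384 genes, 3157 higher and 3227 lower (3209 and 3125 with RLE size factors, 3095 and 2972 with DESeq2), and 3926 with C1 as the control of each line. The small heat shock proteins gave adjusted p = 8.99e-06 with the preset correlation and adjusted p = 0.118 with an estimated correlation. AT1G66100 was at least 917-fold higher in dPrD2 (459-fold against 6 reads), with no reads in WT controls, and AT4G14905 at least 669-fold (335-fold against 6 reads).

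**Figure D3:**
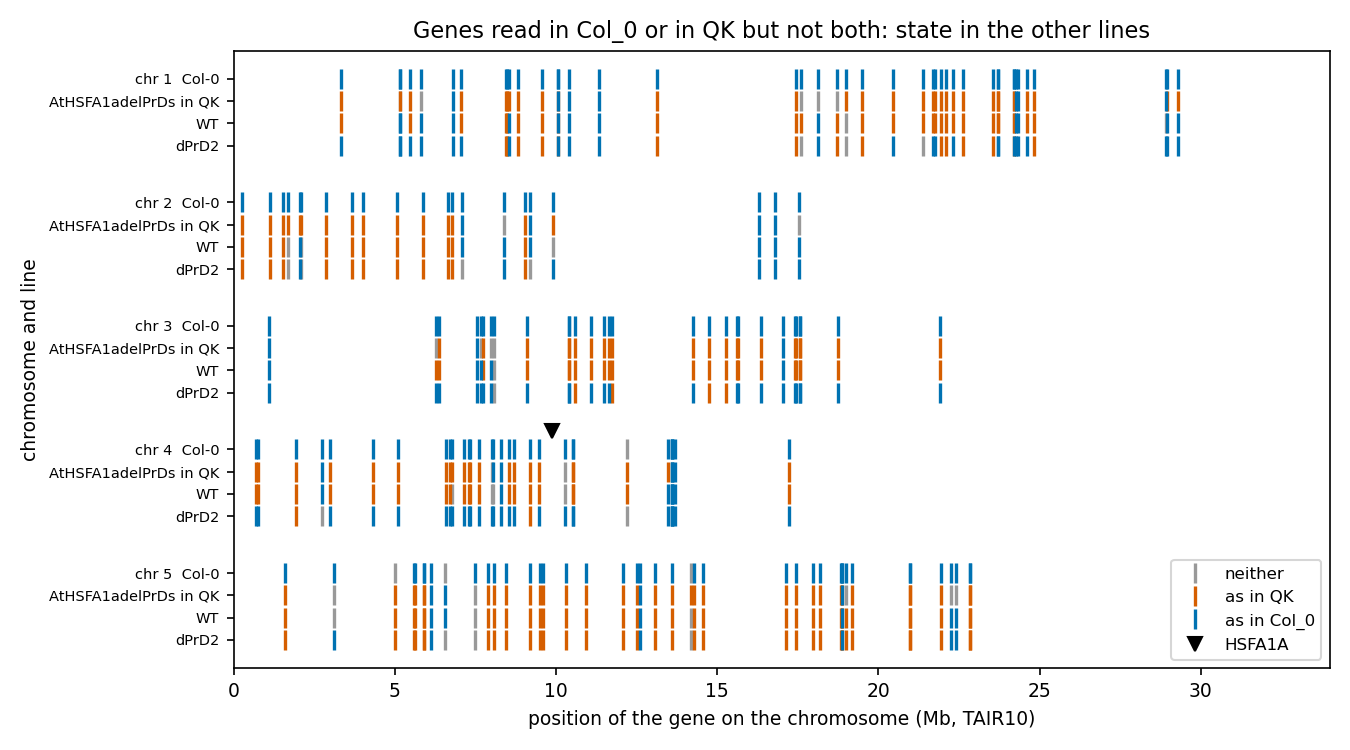
Position, in Mb along each TAIR10 chromosome, of the 166 genes read in one of Col_0 and QK and silent in the other, with 1 tick per gene and line, coloured by whether the gene is in the state of Col_0, the state of QK or neither. The genes read in QK include seed genes such as SESA1, silent in WT and dPrD2. The Col_0 state was found for 162 of the genes in Col-0, 24 in AtHSFA1adelPrDs in QK, 38 in WT and 88 in dPrD2, and the triangle marks HSFA1A on chromosome 4.

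After T, dPrD2 seedlings raised HSFA2 from 0.449 ± 0.533 (C1) and 1.48 ± 0.248 (C2) to 649 ± 17.1 CPM (9.58 ± 0.10) and HSP101 by 6.28 ± 0.05. The 15 small heat shock proteins all rose, 15 adjusted over the list alone (median 6.98, adjusted p = 0.00114), and HSP17.6A reached 522 ± 27.7 CPM, against 890.0 ± 19.2 in WT. The direct test of the difference gave lower responses in dPrD2 for all 15 small heat shock proteins, 15 adjusted over the list alone (median -2.08, adjusted p = 0.00178), with HSP17.6A at -4.04 ± 0.17 and HSP22.0 at -3.07 ± 0.20. Most of these genes started higher in unheated dPrD2, so their levels in T differed less. In a test chosen after the results were seen, T levels were lower in dPrD2 for 14 of 15 (median log2 difference -0.84). HSP22.0 lay at 500 ± 21.1 CPM in dPrD2 T and 719 ± 47.5 in WT T. Cytosolic chaperones had lower responses in 13 of 22 cases and higher ones in 3 (13 and 4 adjusted over the list alone, adjusted p = 0.00148), with HSP90.1 at -1.17 ± 0.07. The chloroplast disaggregase CLPB3 (-1.08 ± 0.05), GOLS1 (-1.55 ± 0.06) and HSFA1E (-1.97 ± 0.21) also had lower responses. GOLS1 too started higher in unheated dPrD2, and in T it lay at 522 CPM in dPrD2 and 695 in WT. Touch and early stress genes had higher responses in 11 of 16 cases and lower ones in 2 (11 and 2 adjusted over the list alone, adjusted p = 0.00178), such as the WRKY factor WRKY40 (2.61 ± 0.28), and so did the salicylate regulator SARD1 (2.40 ± 0.23). Root markers had lower responses in 7 of 10 (9 adjusted over the list alone, adjusted p = 0.00196), such as LRX1 (-1.78 ± 0.23). Most root markers also started higher in unheated dPrD2, and their levels in T were not tested between the lines. Clock genes had lower responses in 8 of 15 (8 adjusted over the list alone with 1 higher, adjusted p = 0.0108), such as PRR7 (-1.12 ± 0.07).

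EdgeR called 10605 genes after T in dPrD2 and 4417 differences from WT, 2254 positive and 2163 negative (2012 and 2353 with RLE size factors, 1948 and 2298 with DESeq2, which turns the larger side), or 2655 differences with C1 as the only control. The difference for HSFA2 passed the test (-0.92 ± 0.31). It no longer did with C1 as the only control (-0.67), with DESeq2 (-0.95), or without dPrD2 C1 replicate 1 (0.42), dPrD2 C2 replicate 1 (-0.84), WT C1 replicate 2 (-0.81) or WT C2 replicate 1 (-0.66), and it was -1.51 without WT C2 replicate 2. Over the 5649 genes that rose in WT after T, the median ratio of the response in dPrD2 to that in WT was 0.676 ± 0.032. The value after ± is the SD over dPrD2 replicates with the WT response held fixed, and the genes were chosen in the same WT libraries. After PT, small heat shock proteins again had lower responses in dPrD2, 15 of 15 and 15 adjusted over the list alone (adjusted p = 0.00406), with HSP17.6A at -4.16 ± 0.16 and HSP22.0 at -3.74 ± 0.19. Most of them started higher in unheated dPrD2, and levels in PT were not tested between the lines. In PT, HSP17.6A lay at 644 ± 4.73 CPM in dPrD2 and 1191 ± 15.4 in WT. Touch genes had higher responses in 12 of 16 cases and lower ones in 1 (13 and 1 adjusted over the list alone, adjusted p = 0.000163), with WRKY40 at 3.14 ± 0.29. Abscisic acid genes had higher responses in 8 of 12 and lower ones in 2 (8 and 2 adjusted over the list alone, adjusted p = 0.0425, and 0.0552 with a replicate block, no longer a call), such as the cold and drought gene COR15A (2.21 ± 0.28). EdgeR called 4465 differences after PT.

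**Figure D4:**
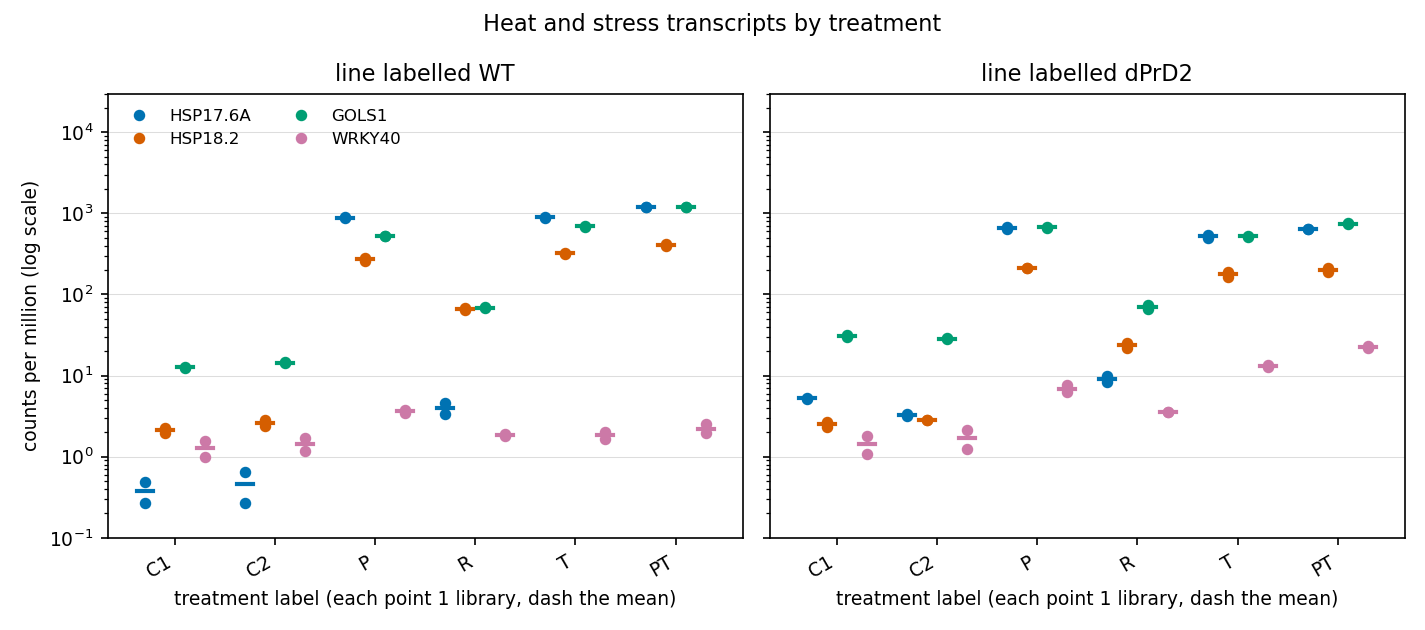
Read level of HSP17.6A, HSP18.2, GOLS1 and WRKY40 in the lines labelled WT and dPrD2, in normalised read counts (CPM) on a log axis, by treatment label, with 1 point per library and a dash at the mean of the 2 libraries of each group. HSP17.6A lies at 0.378 in WT C1 and 890.0 in WT T, and at 5.25 in dPrD2 C1 and 522 in dPrD2 T.

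In R, dPrD2 had the small heat shock protein HSP17.6C-CI at 17.1 ± 0.314 CPM, against 3.79 ± 1.11 in C1 and 4.21 ± 0.486 in C2 (2.08 ± 0.08). HSP18.2 was higher than in the controls by 3.15 ± 0.09 and APX2 by 2.89 ± 0.16, while HSFA1A fell (-0.50 ± 0.06). Of 15 small heat shock proteins 10 were higher and 2 lower (11 and 3 adjusted over the list alone), with adjusted p = 7.01e-09 with the preset correlation. The adjusted p was 0.0480 with an estimated correlation, and it was 0.0547, no longer a call, with the groups in reverse order in the model, and 0.0631 with a replicate block. Salicylate genes were higher in 5 of 8 cases (5 adjusted over the list alone, adjusted p = 0.00165), with SARD1 up by 2.41 ± 0.14. The test against WT R gave lower responses in 13 of 15 small heat shock proteins (14 lower and 1 higher adjusted over the list alone, adjusted p = 0.0356), with HSP18.2 at -1.64 ± 0.14 and HSP17.6C-CI at -1.86 ± 0.16. GOLS1 (-1.11 ± 0.07), APX2 (-1.36 ± 0.23) and HSFA1A (-0.53 ± 0.08) also had lower responses than in WT. A lower response need not be a lower level in R. GOLS1 was higher in unheated dPrD2 by about as much as its response was lower. Most small heat shock proteins also started higher in dPrD2, and levels in R were not tested between the lines. Jasmonate genes had lower responses in 4 of 10 cases (4 adjusted over the list alone, adjusted p = 0.00594), such as VSP1 (-1.67 ± 0.15), and flavonoid genes in 6 of 10 (6 adjusted over the list alone, adjusted p = 0.00205). SARD1 had a higher one (1.86 ± 0.24). The dPrD2 controls C1 and C2 differed for 3207 genes, so the count of calls in R alone does not show what heat on day 4 leaves. EdgeR called 4269 genes in dPrD2 R and 2292 differences from WT, and 1423 differences without WT R replicate 2. AT4G19240 and AT4G15242, genes of chromosome 4, lay at 2.53 ± 1.32 and 1.13 ± 0.304 CPM in dPrD2 R and at 41.2 ± 0.878 and 18.5 ± 1.03 in WT C1. In dPrD2 C1 AT4G19240 lay at 0.0148 ± 0.0209 CPM and AT4G15242 had no reads.

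Between PT and T, dPrD2 had higher APX2 (1.09 ± 0.07) and GOLS1 (0.51 ± 0.04) after PT. Memory genes were higher in 9 of 15 cases (10 adjusted over the list alone, adjusted p = 0.00213), and warm growth and auxin genes in 5 of 7 (5 adjusted over the list alone, adjusted p = 0.00273). ICL, the isocitrate lyase of the glyoxylate cycle, rose from 3.76 ± 0.0799 to 34.6 ± 0.230 CPM (3.20 ± 0.13). Flavonoid genes were lower in 6 of 10 (6 adjusted over the list alone, adjusted p = 0.000864), such as LDOX (-1.52 ± 0.11). The step from T to PT was smaller in dPrD2 than in WT for HSP22.0 (-0.67 ± 0.09), APX2 (-0.60 ± 0.10) and GOLS1 (-0.30 ± 0.06), and more positive for ICL (5.21 ± 0.17) and the abscisic acid gene RD29B (3.11 ± 0.28). HSP22.0, APX2 and GOLS1 do not stand for the list of memory genes. Another gene of that list had a more positive step in dPrD2 (0.59 ± 0.19). Abscisic acid genes differed in 5 of 12 cases (6 positive and 1 negative adjusted over the list alone, adjusted p = 0.00525), and small heat shock proteins in 3 of 15 (3 adjusted over the list alone, adjusted p = 0.278). The dPrD2 controls C1 and C2 differed for 3207 genes, so a count of calls alone does not show an effect of heat on day 4. EdgeR called 4256 genes between PT and T in dPrD2, and 2754 without dPrD2 PT replicate 2. It called 1682 differences from WT, and 1066 without WT PT replicate 1.

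The treatment labelled P is not described in the study text, and heat shock genes rose in it. In WT, HSFA2 lay at 707 ± 1.94 CPM (10.43 ± 0.10) and HSP101 rose by 6.75 ± 0.04. The 15 small heat shock proteins all rose in WT P (15 adjusted over the list alone, adjusted p = 0.00161), and 6 of 8 salicylate genes rose with 1 falling (6 and 1 adjusted over the list alone, adjusted p = 0.0156). In dPrD2 P, HSFA2 rose by 10.02 ± 0.10. Small heat shock proteins had lower responses in dPrD2, 14 of 15 and 15 adjusted over the list alone (adjusted p = 0.0159), with HSP17.6A at -3.68 ± 0.17. Most of them started higher in unheated dPrD2, and levels in P were not tested between the lines. HSFA1A (0.95 ± 0.08) and 15 of 18 photosynthesis genes (16 adjusted over the list alone, adjusted p = 0.0356) had higher responses, such as LHCB1.3 (0.55 ± 0.05). The potassium transporter HAK5 (-3.87 ± 0.15) and the immune receptor kinase FRK1 (-3.34 ± 0.24) had lower responses. EdgeR called 10836 genes in WT P, 11741 in dPrD2 P and 4125 differences.

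The controls C1 and C2 differ in a way the labels do not give. In WT, C2 had more transcripts of 7 of 12 abscisic acid genes (7 adjusted over the list alone, adjusted p = 0.00242), such as COR15A, at 12.5 ± 0.919 CPM in C2 and 1.27 ± 0.498 in C1 (3.29 ± 0.23). Organelle chaperones were lower in 8 of 10 cases (8 adjusted over the list alone, adjusted p = 0.00273), with the chloroplast HSP90.5 at -0.38 ± 0.04. In dPrD2, C2 had higher RD29A, a drought gene (1.16 ± 0.10), and lower organelle chaperones in 9 of 10 (9 adjusted over the list alone, adjusted p = 0.000864). EdgeR called 3822 genes between C1 and C2 in WT and 3207 in dPrD2. Without WT C1 replicate 1 and 2 and WT C2 replicate 1 and 2 it called 2522, 2224, 2339 and 2300 in WT, and without dPrD2 C1 replicate 1 and 2 it called 1913 and 2114 in dPrD2.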

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

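The tests of the differences between responses were planned. The tests of explanations were chosen after the results were seen, except the test of weaker heating of dPrD2, whose prediction was written before. The differences given first were picked out because a test of the difference between 2 responses (an interaction) passed. Of the 3 patterns weighed after them, only the smaller induction in dPrD2 is such a difference, and the others were picked after the results were seen.

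The heat responses of QK and Col_0 differed for 143 genes at 5 min and 1254 at 15 min. At 5 min the log2 difference was -9.99 for HSFA2 (of which -2.69 is a change in QK that was not called), -6.20 for HSP101, -6.54 for BAG6, -5.39 for MBF1C and -3.03 for HSFB2B. At 15 min it was -8.38 for HSFA2, -8.54 for HSP101, -9.44 for HSP70-5 and -4.76 for MTHSC70-2, and it was 1.62 for HSP90.7, 3.69 for CBP60G and 2.59 for YUC8.

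The responses of dPrD2 and WT differed for 4417 genes after T, 4465 after PT, 2292 in R and 4125 in P, and the step from T to PT differed for 1682. After T the difference was -4.04 for HSP17.6A, -3.07 for HSP22.0, -1.17 for HSP90.1, -1.08 for CLPB3, -1.55 for GOLS1, -1.97 for HSFA1E, -1.78 for LRX1 and -1.12 for PRR7, and 2.61 for WRKY40 and 2.40 for SARD1. For HSFA2 it was -0.92, and this call did not hold: it was lost with DESeq2 (-0.95), with C1 as the only control (-0.67) and without dPrD2 C2 replicate 1 (-0.84), WT C1 replicate 2 (-0.81) or WT C2 replicate 1 (-0.66), and the value reversed to 0.42 without dPrD2 C1 replicate 1 (range -1.51 to 0.42 over left-out libraries). After PT it was -4.16 for HSP17.6A, -3.74 for HSP22.0, 3.14 for WRKY40 and 2.21 for COR15A. In R it was -1.64 for HSP18.2, -1.86 for HSP17.6C-CI, -1.11 for GOLS1, -1.36 for APX2, -0.53 for HSFA1A, -1.67 for VSP1 and 1.86 for SARD1. In P it was -3.68 for HSP17.6A, 0.95 for HSFA1A, 0.55 for LHCB1.3, -3.87 for HAK5 and -3.34 for FRK1. For the step from T to PT it was -0.67 for HSP22.0, -0.60 for APX2, -0.30 for GOLS1, 5.21 for ICL and 3.11 for RD29B.

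The list tests of these differences after T gave adjusted p = 0.00178 for small heat shock proteins, 0.00148 for cytosolic chaperones, 0.00178 for touch genes, 0.00196 for root markers and 0.0108 for clock genes. After PT they gave 0.00406 for small heat shock proteins, 0.000163 for touch genes and 0.0425 for abscisic acid genes, which a replicate block brought to 0.0552, no longer a call. In R they gave 0.0356 for small heat shock proteins, 0.00594 for jasmonate genes and 0.00205 for flavonoid genes. In P they gave 0.0159 for small heat shock proteins and 0.0356 for photosynthesis genes, and for the step from T to PT 0.00525 for abscisic acid genes.

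The first pattern weighed is the high small heat shock protein transcripts in unheated AtHSFA1adelPrDs in QK. Heating under a 22 °C label would raise genes that heat also raises in QK, but against Col_0 at 22 °C the median of 287 such genes was 0.26 on the log2 scale (quartiles -0.32 and 1.08, against 2.77 in Col_0 after 15 min), and HSFA2 lay at 0.166% of its level there, with the reads of each group summed over its libraries. Heated Col_0 seedlings mixed in would need a share of 19.5%, the median level of the listed small heat shock proteins in this line relative to Col_0 at 15 min. As mixing only adds reads, every gene read in Col_0 and silent in QK would have to reach that share of its level in Col_0 at 15 min. Of 105 such genes, with none left out, 91 lay below it by their own upper 95% limit (89 if every fragment gave 2 reads) and 66 had no reads, while 16 were read at 10% or more of their level over all Col_0 libraries. All 105 together were read at 5.92% (95% interval 5.73% to 6.12%, or 5.65% to 6.20% if every fragment gave 2 reads). The level of HSFA1A, 28.3 times that of unheated Col_0 by summed reads, cannot be told apart from the deleted domains, since no line has the whole protein at that level. Activity of the factor without its prion-like domains at 22 °C stays a hypothesis, untested.

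The second pattern is the smaller induction of small heat shock proteins in dPrD2 after T. If weaker heating were the cause, 274 heat genes chosen in the other sets would respond less too, but their median difference was -0.039 with quartiles of -0.61 and 0.83, which decides nothing. A higher unheated level alone is argued against, since the heated levels of these genes in dPrD2 lay below those in WT by a median log2 difference of -0.84, with 14 of 15 called lower. The HSFA1A level in unheated dPrD2 (-0.77 against WT) cannot be told apart from the domain the line is named for, as both go with the line. The domain, the level and other differences between the lines may each contribute, and none was tested alone.

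The third pattern is the set of genes read in one line and silent in another. Chromosome segments from another parental genome may account for it, since in dPrD2 the state of 153 such genes switched 41 times along the chromosomes, against a median of 73 and a minimum of 48 in 10000 shuffled orders (permutation p = 1e-04, the smallest these can give), and with the stricter limits tried first 51 genes switched 15 times, against a median of 23 and a minimum of 11 (permutation p = 0.01). Silence can also be a difference of expression: genes read in QK include seed genes, silent in WT and dPrD2. The 101 genes read in Col_0 switched 15 times, against a median of 48 (permutation p = 1e-04), and the 52 read in QK 16 times, against a median of 23 (permutation p = 0.02). Seedlings of WT mixed into dPrD2 R remain open: genes silent in dPrD2 controls were read at 7.11% of the WT level on chromosome 4 (9 genes) and at 4.34% elsewhere (3 genes, 95% interval 2.53% to 6.95%, or 1.93% to 8.38% if every fragment gave 2 reads), while a first limit of 2 CPM gave 7.22% and, from 1 gene, 0 with an upper limit of 1.65% (3.29% in that case), which would have argued against mixing. The share elsewhere was 5.19% in dPrD2 T, 3.42% in P and 3.10% in PT, where chromosome 4 lay at 0.671%, 0.102% and 0.266%. These shares are no background for R, as they came from another gene. APD3 gave 11 of 11 reads in T, 24 of 24 in P and 8 of 9 in PT, but 2 in R. In R, 15 of the 17 reads elsewhere came from AT5G52067, which had none in T, P, PT and the dPrD2 controls, as mixing would give. AT3G49020 had none in R where the WT level would give 224, which mixing would not give. With 3 genes that differ in this way, mixing is neither shown nor excluded. Col_0-type seedlings mixed into dPrD2 T are argued against, since such genes were read at 3.74% on chromosome 2 (8 genes) and at 0.187% elsewhere (31 genes, 95% interval 0.129% to 0.262%, or 0.108% to 0.301% if every fragment gave 2 reads). A segment that still segregates in dPrD2 is a further hypothesis and was not tested.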

How the results depend on the processing

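The alternatives without the genes read in one of Col_0 and QK and silent in the other, without the genes of a chromosome, with the groups in reverse order and with a replicate block in the list tests were chosen after seeing the data, and the others were planned. Counts of called genes stayed within 1.5 times in 27 of 27 comparisons with RLE size factors and in 27 of 27 with a replicate block, in 25 with DESeq2, 23 with no filter, 24 of 26 with only the groups compared, 13 of 13 with C2 and 11 of 13 with C1 as the control, and all 18 without the genes silent in Col_0 or QK. Of 1955 values of named changes under the alternatives, 1946 kept direction and side of the threshold, 8 lost the call and 1 reversed, HSFA2 in the difference between dPrD2 and WT after T (0.42 without dPrD2 C1 replicate 1, range -1.51 to 0.42 over left-out libraries). The cause of the moves was not tested, except that fewer libraries or more genes tested follow from an alternative's construction.

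With no filter the counts were 2379 for Col_0 at 5 min, 703 for QK at 5 min, and 591 and 2254 for the difference between them at 5 and 15 min. DESeq2 gave 376 for QK at 5 min and 297 for the difference. With only the groups compared, Col_0 at 5 min gave 715 and QK at 5 min 120. With C1 as the control, the difference after T gave 2655 and dPrD2 against WT 3926. Called list tests in the first set were 0, 73 with the preset correlation and 80 with fry. In the Col-0 set they were 0, 13 and 11, and in the third 139, 190 and 284. The sets differ in residual degrees of freedom (7, 2 and 12), so these counts do not compare how far the lists moved. With the groups in reverse order they were 0, 0 and 139, of which 138 were called in both orders. With a replicate block they were 0, 0 and 137, of which 136 were called without it too. The block ended the calls of small heat shock proteins in dPrD2 R (adjusted p = 0.0631) and of abscisic acid genes in dPrD2 T (0.0552) and in the difference after PT (0.0552), and added cytosolic chaperones in the difference in P (0.0322). In the first set, where replicate numbers go with header prefixes, deviations of replicate 1 from the group mean correlated between pairs of groups by -0.373 to 0.15, with 3 of 21 pairs over 0.1 and 3 under -0.1. With changes of at least 2-fold, the shares in the same direction were 98.9%, 97.3% and 93.6%, in the order given in the report. On genes chosen in other sets, the median response ratio was 0.275 in QK at 5 min and 0.42 at 15 min, 0.754 in dPrD2 after T and 0.804 after PT, against 0.296, 0.367, 0.676 and 0.685. After PT the median response of these 809 genes was higher in dPrD2 (0.7254) than in WT (0.6942), against a median ratio below 1, so the direction after PT depends on the summary for these genes. For QK, the genes chosen in another set had a median log2 response in Col_0 of only 0.172 at 5 min and 0.2815 at 15 min. Many of their ratios divide by values near 0, so for QK these ratios are a weak check. Without chromosome 4 genes, dPrD2 R gave 3531 genes and its difference 1930. Without chromosome 2 genes, dPrD2 T gave 8981 and its difference 3777.

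Leaving out each library in turn leaves an arm with 1 library, assumed to vary like the other groups. The counts then ranged from 414 to 1439 for Col_0 at 5 min, 2976 to 4191 at 15 min, 7 to 98 for QK at 5 min, 1353 to 1729 at 15 min, and 92 to 197 and 717 to 1112 for the differences. They ranged from 5050 to 6786 for Col-0, 2657 to 3778 for WT R, 2360 to 2435 for WT PT against T, 2224 to 2522 for C2 against C1 in WT and 1913 to 2232 in dPrD2, 2754 to 3308 for dPrD2 PT against T, 1423 to 2214 for the difference in R and 1066 to 1380 for that in the step from T to PT. Scaling moved the median of all genes by at most 0.041 on the log2 scale. RLE size factors turned which direction held more called genes for WT T, WT PT, WT P, dPrD2 P, dPrD2 C2 against C1, dPrD2 against WT, the difference after T and that in the step from T to PT, and DESeq2 turned all of these but the last. On simulated data, changes of 1.5-fold were recovered in 2.99% to 74.6% of cases, depending on the comparison, and of the calls 17.42% were false with DESeq2 and 5.22% with edgeR for Col_0 at 5 min, 11.43% and 9.35% for Col-0 at 37 °C, and 6.18% and 6.11% for WT after T. DESeq2 was run on simulated data for these 3 comparisons only.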

Other observations

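The tests of this part were chosen after seeing the results. To compare the lines, genes were taken that were read at 2 CPM or more in one of Col_0 and QK and at 0.1 CPM or less, and 2% or less of that level, in the other, which gave 166 genes, 105 read in Col_0 and 61 in QK. These are differences of expression, which need not mark a line: those read in QK include seed genes such as SESA1, SESA5 and ATPXG2, whose silence in WT and dPrD2 counts as the Col_0 state. Of the 166 genes, 162 had the Col_0 state in Col-0, 24 in AtHSFA1adelPrDs in QK, 38 in the line labelled WT and 88 in dPrD2. In dPrD2 the Col_0 state was found for 27 of 31 such genes on chromosome 4, 24 of 29 on chromosome 3, 25 of 43 on chromosome 1, 6 of 21 on chromosome 2 and 6 of 42 on chromosome 5. Of the genes read in Col_0 alone these were 17 of 18, 22 of 23, 16 of 25, 1 of 12 and 2 of 27, in the same order. The nearest such genes to HSFA1A, AT4G16870 (read in Col_0) at 386 kb and AT4G18690 (read in QK) at 413 kb, both had the Col_0 state in dPrD2. AT4G18690 had neither state in WT. The next such gene beyond AT4G16870, AT4G16215 (read in QK), had the QK state in dPrD2, at 19.2 CPM. AT4G16870 was read at 0.0509 CPM over all WT libraries and at 71.9 CPM over all dPrD2 libraries. Leaving these 166 genes out changed the count of dPrD2 against WT from 6384 to 6304.

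Within groups, the spread between the 2 libraries was above counting error in each set: the mean chi-square per gene with at least 40 reads was 9.16 to 22.4 in the first set, 21.0 to 43.6 in the Col-0 set and 3.09 to 5.04 in the third. Counting error alone gives about 1, or about 2 if every fragment gave 2 reads. The first principal component took 62.7%, 89.1% and 43.1% of the variance in the 3 sets.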
